A study of Mus musculus with 2 samples.

How the data were processed

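DNA of mononucleosomes from female mouse liver was sequenced in 1 library of nucleosomes purified for the histone variant macroH2A1 and 1 library of the bulk nucleosomes that the purification started from. Per the labels, frozen livers of mice aged 8 to 10 weeks were used, chromatin was cut with micrococcal nuclease after removal of histone H1, and thiol-affinity columns separated nucleosomes with macroH2A1, which 1 resin binds and another does not. The labels also state that livers lacking macroH2A1 gave no purified nucleosomes; that control was not used here. DNA of 2 preparations was pooled before sequencing.

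The deposited read positions are on mouse build mm8, each for a read of 25 bases with a single placement; the aligner is not given in the sources used here. Each library came in 3 parts, told apart by the files themselves: a first block of reads with intervals 24 wide, a second block with intervals 25 wide, and the third part, with read sequences from 1 lane. The alignment score deposited with each read of the third part was made by the aligner, with a scale not given in the sources used here, and no filter was put on it. Read counts per transcript were made by the authors with Partek 6.5b, from a refFlat list described as having its exons removed. Each count covers the whole interval between the start and stop of the transcript, reads in exons included, as the match given below shows. The RPKM values, reads per kilobase of that interval scaled to the reads of the library, were computed by the authors in the same program. The signed fold change in the deposited table is the ratio of both RPKM values, written as a negative reciprocal where macroH2A1 is lower and left out where a count is 0. The p-value of each transcript and its FDR adjustment were computed by the authors, with a test not named in the sources used here. The deposited counts lay within 1 read of counts made here from the same intervals for 26337 and 26339 of 26339 transcripts, allowing for either rule on reads that cross an interval's end.

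Own counts started from the read positions of all 3 parts together. A read was placed at the centre of its fragment, 73 bp from its 5′ end; ends of opposite strands were most often 167 and 168 bp apart in the macroH2A1 and bulk libraries. Each gene symbol was given 1 interval per chromosome, that of its longest transcript, and 21229 genes on autosomes and X were counted. Ratios of macroH2A1 to bulk reads were scaled to the autosomal reads, 11048589 and 11898581. Exact (Clopper-Pearson) 95% intervals came from the binomial share of macroH2A1 reads among the reads of both libraries. A gene with at least 60 reads over both libraries was called higher or lower where its interval excluded 1; 14364 genes had enough reads, and the median autosomal gene among them had 252. No test between groups was run, since there was 1 library per group. Of all reads, 2.57% and 1.59% repeated the position and strand of another read of their library, and 78.2% and 80.4% had no mismatch, a share that differed between the parts, from 21.6% and 10.4% in the first to 92.4% and 92.0% in the third.

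Gene lists were fixed, with the comparisons, thresholds and most alternatives, before the data were examined. For a list, reads were pooled over all autosomal members, members with at least 60 reads were counted by call, and the median of their log2 ratios was placed among 10000 random lists of the same size. Random members were drawn with replacement from genes in the same of 20 bins of total reads. For X-linked lists, which were set against X genes, 5 bins were used. Members were drawn singly, so that a list whose genes lie side by side can look rarer than it is. The lists cover secreted liver proteins, liver enzymes and transporters, liver transcription factors, lipid metabolism, sex-biased and zonal liver genes, ubiquitous, proteasome, ribosomal and oxidative phosphorylation genes, neuronal, muscle, germ cell and developmental genes, receptor, keratin, zinc finger, histone and protocadherin families, markers of other liver cells, cell division, imprinted genes, histone variants and X-linked genes. The division of the autosomal genes at the dip of their distribution was made after seeing the data.

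Named genes were chosen by a rule on the limits of their intervals, among genes of at least 1 kb with enough reads. These are the 8 autosomal genes with the highest lower limit, the 8 with the lowest upper limit and 4 X-linked genes at each end, passing over a gene that overlaps one already chosen, which happened 1 time. Up to 2 members at each end of each list were added, and Xist, H2afy, Alb, Apoa1, Serpina7, Cyp7a1 and Lpl whatever their reads. Some genes that this rule names are not reported here. Named windows are the 5 highest and 5 lowest autosomal windows and 2 at each end on X.

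Start sites were compared within 200 bp with flanks 2 to 3 kb away on both sides, and gene bodies of 10 kb or more were divided into a first 1 kb and 10 equal parts. Windows of 1 Mb with at least 200 reads were compared with 100 simulations of counting error. GC content was taken from bulk reads of the third part, for windows with at least 20 and genes with at least 10 such reads. The intervals were tested on simulated data for 13750 genes, with Poisson counts in both libraries. Of 13222 unchanged genes 2.19% were called higher and 2.07% lower. Of genes changed 1.5-fold, 2-fold and 4-fold, 86.4%, 98.4% and 100% were called in the right direction. The simulation held no variation between preparations or libraries, so these shares cover counting error only.

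Alternatives covered the scaling, repeated positions, the placement of reads, the minimum of reads, the interval level, the first 1 kb of genes, overlapping genes, the GC content, window sizes and the authors' deposited RPKM values; use of each sequencing part alone and of reads without a mismatch was added after seeing the data. Reads on the Y chromosome and the mitochondrial genome were left out of the comparisons. Only reads with a single placement are in the files, so gene families with near copies are thinly covered. Strand was used only to find fragment centres, and reads in overlapping genes were counted for each. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.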

Results

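The distribution of macroH2A1, a variant of histone H2A that carries a large globular domain at its carboxyl end, was measured in the liver of female mice. The macroH2A1 library holds DNA of mononucleosomes purified for this variant, and the bulk library holds DNA of the nucleosomes from which they were purified, so that each value below is a ratio of macroH2A1 to bulk nucleosomes at the same place in the genome. There was 1 library per group, made from the pooled DNA of 2 preparations of 8 to 10 livers each. The macroH2A1 library had 12468289 placed reads and the bulk library 12460356. Each came in 3 parts that the labels do not describe. They are taken as repeat sequencing of the same pooled DNA, not as biological replicates, though they differ in mismatch share and in read density at start sites; whether they come from 1 preparation of the library is not known. The parts held 1392902, 2612910 and 8462477 reads for macroH2A1 and 872746, 2729300 and 8858310 for bulk. No ratio has a replicate check. The 95% intervals cover counting error only, since there was 1 library per group. They take each read as independent. PCR reads without molecular identifiers are not independent molecules, so the intervals can be too narrow. Values of the 3 parts are given for the main results and for some single genes. Coordinates are of mouse build mm8.

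The first comparison asks how macroH2A1 nucleosomes are shared between the X chromosome and the autosomes in female cells, where 1 of the X chromosomes is inactive. The X chromosome was 2.73-fold higher in macroH2A1 nucleosomes than in bulk nucleosomes relative to the autosomes (95% interval 2.72 to 2.73). It took 11.4% of the macroH2A1 reads and 4.50% of the bulk reads (95% Wilson intervals 11.4 to 11.4% and 4.49 to 4.51%). The 19 autosomes lay between 0.899-fold on chromosome 14 and 1.08-fold on chromosome 9, with an SD of 0.0852 on the log2 scale, against a log2 ratio of 1.45 for X. The excess ran along the whole chromosome: 159 of 160 X windows of 1 Mb had an interval above 1, with a median of 2.65-fold, and none had an interval below 1. The X ratio was 2.75-fold inside gene bodies and 2.71-fold outside them. The 3 sequencing parts gave 2.40-fold, 2.64-fold and 2.81-fold, which differ by more than counting error.

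**Figure D1:**
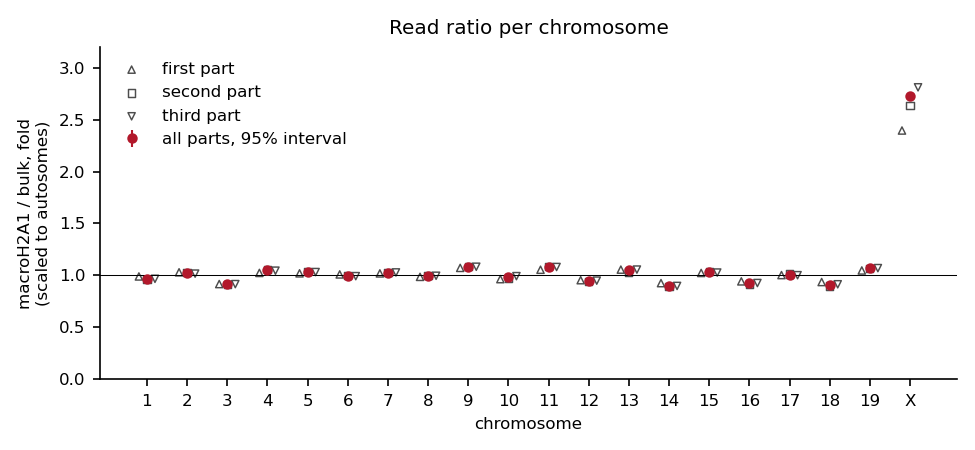
Ratio of macroH2A1 to bulk reads on each chromosome (vertical axis, fold, scaled to all autosomes), as red circles with 95% intervals that are smaller than the symbols, and in each of the 3 sequencing parts as open symbols. The autosomes lie between 0.899 and 1.08 and the X chromosome at 2.73.

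Nearly all X-linked genes shared this excess. Of 614 X-linked genes with at least 60 reads over both libraries, 604 were higher in macroH2A1 nucleosomes, 6 were lower and 4 were undecided, with a median log2 ratio of 1.48. All 26 members of the list of X-linked ubiquitous or liver genes were higher, with a pooled ratio of 2.90-fold (2.83 to 2.98). They included Flna (filamin A) at 3.98-fold, Msn (moesin) at 3.24-fold, and at the low end Atrx, a chromatin remodeller, at 2.45-fold. All 19 X-linked neuronal or muscle genes were higher too, at 2.69-fold pooled (2.66 to 2.73; the pooled log2 ratio of X-linked neuronal or muscle genes was 1.43, and 2.02 with the GC trend of windows removed), from Nlgn3 at 3.71-fold and Dcx at 3.36-fold down to Cnksr2 at 2.18-fold and Pcdh11x at 1.56-fold. The medians of these lists lay at the 92.5th and 21.6th percentiles of 10000 random lists of X genes matched on reads. Serpina7, which encodes the thyroxine-binding globulin, was 2.89-fold higher (1.91 to 4.49). The highest lower limits belonged to Plxnb3 at 4.34-fold, Flna, Gpr64 at 3.64-fold and Trap1a, which rested on 72 and 12 reads, at 6.46-fold (3.48 to 13.1).

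The few X-linked genes that were lower included genes known to escape X inactivation, that is, to be transcribed from both X chromosomes. Kdm5c, a histone demethylase and escape gene on X from 147573945 to 147615070, was 5.45-fold lower (3.85 to 7.90), and Eif2s3x, a translation initiation factor subunit, was 3.21-fold lower (2.16 to 4.88). The other genes at this end were 2010000I03Rik, 6.85-fold lower on 8 and 59 reads, and B230206F22Rik, 3.13-fold lower, both on the side of Xist with higher coordinates. Xist, the RNA gene that is transcribed from the inactive X, was 1.71-fold lower (1.22 to 2.41), over an interval that another annotated gene overlaps. The sixth, 5530601H04Rik, a member of the list of escape genes, was 2.58-fold lower and was singled out after its value was seen. Of the 8 escape genes with enough reads, 4 were lower, 3 were higher and 1 was undecided. The higher ones were Car5b at 2.84-fold, Shroom4 at 2.57-fold and Mid1, singled out in the same way, at 2.18-fold. Shroom4 and Mid1 are long and held 2890 and 3692 of the list's 7840 macroH2A1 reads, and the pooled log2 ratio of 0.98 and the median of members of -0.51 have opposite signs. None of 10000 random X lists had a median as low.

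The second comparison asks which genes are rich or poor in macroH2A1. Autosomal genes were more often poor: of 13750 with enough reads, 3438 were higher in macroH2A1 nucleosomes, 8014 were lower and 2298 were undecided. The median gene was 1.71-fold lower, with quartiles of -2.11 and 0.35 on the log2 scale. The values, looked at as a distribution after they were seen, fell into 2 groups, one with its peak between log2 ratios of -2.5 and -2.25 (1200 genes) and one between 0.25 and 0.5 (901 genes), with a dip between -1.25 and -1 (480 genes). In all, 1364 autosomal genes were at least 4-fold lower by the upper limit of their interval and 525 at least 2-fold higher by the lower limit. Autosomal reads inside gene bodies were 1.29-fold lower in the macroH2A1 library; as ratios are scaled to all autosomal reads, this sets those outside at 1.16-fold higher.

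The autosomal genes with the highest lower limits were led by Slc36a2, an amino acid transporter gene on chromosome 11 from 55001890 to 55028500, at 6.36-fold (5.43 to 7.48), and Tekt3, a sperm tail tektin gene on chromosome 11 from 62877853 to 62911155, at 6.04-fold (5.27 to 6.95). Kcnh6, a potassium channel gene, was 5.82-fold higher and Pak6, a kinase gene, 5.47-fold. On chromosome 9, Pkm2, which encodes the muscle-type pyruvate kinase, was 5.79-fold higher and Nr2e3, a nuclear receptor of photoreceptors, 6.03-fold. Btbd16 was 4.79-fold higher. Igf2as, at 6.83-fold, with log2 ratios of 1.3, 2.73 and 3.10 in the parts, overlaps Igf2, a fetal growth factor gene, and reads without strand assignment could not be split between them.

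The genes with the lowest upper limits included several that every cell uses. Canx (calnexin, a chaperone of the endoplasmic reticulum, on chromosome 11 from 50137379 to 50169096) had 7 macroH2A1 reads and 120 bulk reads and was 15.9-fold lower (7.49 to 40.4). Ndufa9, a subunit of respiratory complex I, was 12.5-fold lower and Ptbp2, a splicing regulator, 13.4-fold. Ddx56, an RNA helicase gene, had 4 and 94 reads (21.8-fold lower, 8.25 to 81.7), and Bap1, a deubiquitinase gene, 2 and 66 reads (30.6-fold lower, 8.15 to 258). Fam116a and 5830418K08Rik were 10.9-fold and 12.4-fold lower, the latter over an interval shared with another gene. H2afy, the gene of macroH2A1 itself, on chromosome 13 from 56083244 to 56145172, was 6.39-fold lower (4.93 to 8.40).

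**Figure D2:**
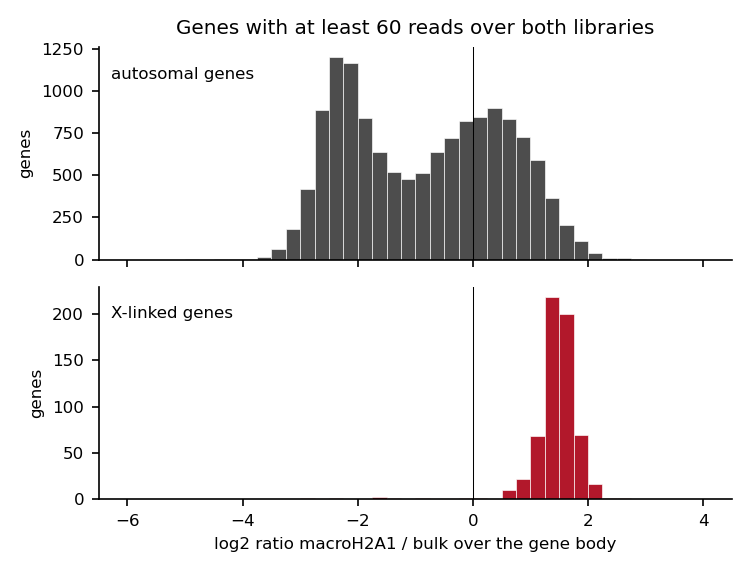
Number of genes (vertical axes) by log2 ratio of macroH2A1 to bulk reads over the gene body (horizontal axis, steps of 0.25), for autosomal genes above and X-linked genes below, with at least 60 reads over both libraries. Autosomal genes form 2 peaks, of 1200 genes near -2.5 and 901 genes near 0.5, and X-linked genes form 1 peak around their median of 1.48.

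Most of these calls had the same direction in each sequencing part, whose reads are also included in the calls. Among called autosomal genes with at least 20 reads in a part, 90.6% of the higher and 96.9% of the lower genes had the same sign in the first part, 97.4% and 99.3% in the second, and 100% and 99.99% in the third, which supplies most of the reads. The zero of the ratio depends on the scaling: the median of all genes moved by -0.11 on the log2 scale when the X was counted in the library size and by 0.17 when the median 1 Mb window was set to 1.

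Genes that every cell uses were the poorest in macroH2A1 of the lists fixed beforehand. Of 20 ubiquitous genes with enough reads, 19 were lower, none was higher and 1 was undecided, and the list was 5.38-fold lower over all its reads (4.90 to 5.92). Besides Canx, Cltc (the clathrin heavy chain) was 7.43-fold lower, while Gusb was 2.03-fold lower and Eef2, at 1.19-fold lower (0.731 to 1.95), was not distinguishable from 1. Of 21 proteasome genes, 20 were lower and none was higher, at 4.32-fold lower pooled (3.99 to 4.69), with Psmd11 at 10.5-fold lower and Psmb7 at 7.09-fold. The exception was Psma8, the proteasome subunit specific to the testis, with a ratio of 0.893 (0.755 to 1.06). It held 258 of the 735 macroH2A1 reads of the list, whose median of members was -2.73. All 20 oxidative phosphorylation genes were lower, at 4.31-fold pooled (4.0 to 4.63), from Ndufa9 and Ndufs4, 5.67-fold lower, to Cox7b2, 1.69-fold lower. The first sequencing part gave smaller drops than the others: the log2 ratios in the first, the second and the third part were -1.68, -2.63 and -2.59 for ubiquitous genes, -1.40, -2.23 and -2.22 for proteasome genes, and -1.41, -2.21 and -2.26 for oxidative phosphorylation genes. For each of these 3 lists, none of 10000 random autosomal lists of the same size and reads had a median as low. Among ribosomal protein genes, which are short and of which only 3 had enough reads, Rps15a was 7.02-fold lower and Rpl22 4.83-fold, and Rpl3l, a form used in muscle, was 1.80-fold higher (1.20 to 2.74). The ribosomal protein list was 3.60-fold lower over all its reads (3.11 to 4.18).

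Hepatocyte genes were lower as well, but less so, and their medians did not stand out from those of random lists. Of all 13750 autosomal genes with enough reads, 58.3% were lower, and their median log2 ratio was -0.77. The median was -0.77 for secreted liver proteins, against -1.215 for random lists matched on reads. For metabolic enzymes and transporters it was -1.14, against -1.23. Of 37 genes of secreted liver proteins, 21 were lower, 1 was higher and 15 were undecided, and the list was 1.81-fold lower (1.73 to 1.90), at the 78.7th percentile of random lists by its median. Serpind1 was 7.02-fold lower, over an interval shared with another gene, whereas A1bg was 2.02-fold higher (1.36 to 3.04) and F12 stood at 1.35-fold (0.849 to 2.15). Alb, the serum albumin gene, had 27 macroH2A1 and 47 bulk reads, a ratio of 0.619 whose interval reached 1.01 and log2 ratios of -3.18, -2.65 and -0.26 in the parts, and Apoa1, with 11 and 5 reads, was not resolved (0.759 to 8.70). Of 37 metabolic enzyme and transporter genes, 26 were lower, 3 were higher and 8 were undecided, at 1.89-fold lower pooled (1.80 to 1.98) and the 57.1st percentile. Cpt1a, which carries fatty acids into mitochondria, was 4.48-fold lower, while Cyp2e1 was 3.26-fold higher (2.45 to 4.39). Sds was 1.85-fold higher and overlaps another gene. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 1.02-fold (0.634 to 1.64).

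Liver transcription factor genes were 2.60-fold lower over all reads (2.47 to 2.73), with 10 of 15 lower, none higher and 5 undecided. Esr1 and Ghr held 1954 and 1075 of the 5986 bulk reads, and the median of members was -0.79. The estrogen receptor gene Esr1 was 3.8-fold lower and Ghr, the growth hormone receptor gene, 3.64-fold, while Hnf4a, a main hepatocyte regulator, stood at 1.25-fold (0.970 to 1.61). The median of this list lay at the 46.8th percentile. Of 29 lipid metabolism genes, 20 were lower, 4 higher and 5 undecided, at 1.65-fold lower (1.59 to 1.72) and the 31.1st percentile. They spanned a wide range: Gpam, 8.75-fold lower, stood against Scd2, a stearoyl-CoA desaturase gene, at 4.34-fold higher (3.47 to 5.47) and Cidea, a lipid droplet gene of brown fat, at 2.22-fold higher over an interval shared with another gene. Lpl, the lipoprotein lipase gene, was 1.37-fold lower (1.05 to 1.81).

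Genes of the liver lobule's zones and of sex-biased expression varied by gene. Of 12 pericentral genes, 3 were higher, 4 were lower and 5 were undecided. Their pooled ratio of 1.71-fold higher (1.63 to 1.79) rested on Slc1a2, a glutamate transporter gene that held 2707 of the 4423 macroH2A1 reads and was 2.95-fold higher; the median of members was 0.03. Oat was 3.74-fold higher, and Ahr and Cyp27a1 were 3.63-fold and 2.36-fold lower. Of 14 periportal genes, 7 were lower, 3 were higher and 4 were undecided, at 1.21-fold lower pooled (1.13 to 1.29). That call was lost, at a log2 ratio of -0.10, when the median 1 Mb window was set to 1, and the parts gave -0.62, -0.26 and -0.24. Cps1 and Asl of the urea cycle were 3.34-fold and 3.65-fold lower, and Cyp2f2 was 2.78-fold higher, with a log2 ratio of -0.0052 in the first sequencing part. The medians of both zonal lists lay at the 90.8th and 80.8th percentiles. The pooled ratios of female-predominant genes, 0.978 (0.933 to 1.03), and male-predominant genes, 1.00 (0.953 to 1.05), were not distinguishable from 1 with autosomal scaling; under either other scaling both lists moved to one side of 1, the side depending on the scaling. Among 13 female-predominant genes 4 were higher and 3 lower, with Cyp3a16 at 4.26-fold and Cyp3a44 at 2.33-fold higher and Abcd2 and Tox 3.07-fold and 2.41-fold lower. Among 13 male-predominant genes 3 were higher and 6 lower, with Susd4 at 1.51-fold and Elovl3 at 1.77-fold higher and Bcl6 and Cyp7b1 3.56-fold and 1.96-fold lower. The female list stood at the 91.6th percentile and the male list at the 80.2nd. Against lists matched on GC content instead, the female and male medians lay at the 98.9th and 90.7th percentiles. The pericentral and periportal medians then lay at the 89.9th and 55.9th.

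Genes of other tissues were mostly at or above the genome's level. Of 136 autosomal homeobox and developmental transcription factor genes, 78 had enough reads, of which 52 were higher, 1 was lower and 25 were undecided. Over all members the list was 1.67-fold higher (1.64 to 1.71), with log2 ratios of 0.36, 0.79 and 0.77 in the parts. Lhx2 was 3.15-fold higher, Tbx20 was 1.26-fold lower, and Pax9 stood at 0.673 (0.442 to 1.01). Of 95 keratin genes, 43 had enough reads, of which 25 were higher and none lower, and the list was 1.77-fold higher over all members (1.70 to 1.85). Krt79 led at 4.51-fold and Krt23 at 3.68-fold, with Krt13 and Krt36 at 0.683 and 0.718 and intervals that include 1. The minimum counts reads of both libraries, so a short gene reaches it more easily where macroH2A1 is high. In lists of short genes the counts by call and the medians can therefore lean toward higher genes. None of 10000 random lists had a median above that of the developmental or the keratin list. Random lists drew genes singly, whereas neighbouring regions are alike (r = 0.524 between neighbouring 1 Mb windows). For genes that lie in clusters this can overstate how rare a median is. Of 36 muscle contractile genes, 24 were higher, 5 lower and 7 undecided, at 1.20-fold (1.17 to 1.22): Myl2, a cardiac myosin light chain gene, was 3.04-fold higher and Nrap 2.93-fold, while the giant genes Ttn and Neb were 1.66-fold and 1.67-fold lower. Of 27 germ cell genes, 15 were higher and 3 lower, at 1.40-fold (1.35 to 1.45), with Tdrd1 at 3.19-fold and Gdf9 at 2.91-fold higher and Nlrp5 and Boll 1.70-fold and 1.52-fold lower. The muscle and germ cell medians lay at the 99.99th and 99.8th percentiles. The long neuronal genes differed: of 67, 51 were lower and 12 higher, at 1.31-fold lower (1.3 to 1.32). Their median lay at the 1.23rd percentile of lists matched on reads but at the 99.89th of lists matched on GC content, their members having a median GC content of 44.5%. Gabrg3 was 2.32-fold lower, against Grin1 at 2.14-fold and Syn2 at 1.66-fold higher.

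**Figure D3:**
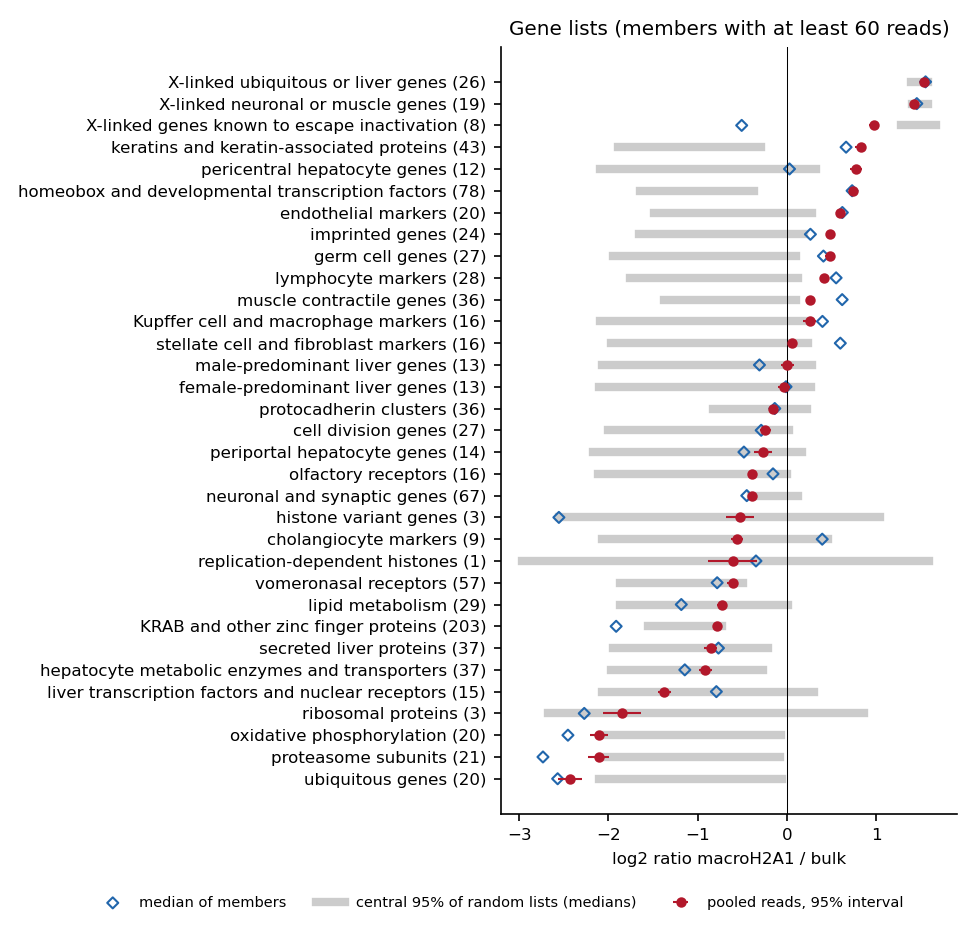
Log2 ratio of macroH2A1 to bulk reads (horizontal axis) for the gene lists fixed beforehand, with the number of members with at least 60 reads in parentheses: pooled reads with 95% interval (red), median of members (blue diamonds) and the central 95% of medians of 10000 random lists matched on reads (grey; drawn from X genes for X-linked lists). Ubiquitous, proteasome and oxidative phosphorylation genes lie lowest, at 5.38-fold to 4.31-fold lower, and developmental transcription factors and keratins lie above their random lists; only the protocadherin list changes the side of 0 of a called pooled value with the scaling.

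Markers of the other liver cell types, whose nuclei the chromatin also holds, were mostly higher. Of 20 endothelial genes, 15 were higher and 1 lower, at 1.51-fold (1.47 to 1.56), with Pecam1 at 2.77-fold and Lyve1 at 2.99-fold; Tek stood at 1.00-fold (0.898 to 1.12), and Emcn was 1.29-fold lower in all reads but had a log2 ratio of 0.25 in the first part. Of 28 lymphocyte genes, 17 were higher and 1 lower, at 1.33-fold (1.29 to 1.38). Ccr7 was 3.01-fold and Cd3e 2.68-fold higher, Ikzf1 was 1.52-fold lower, and Prkcq stood at 0.922 (0.833 to 1.02). Of 16 Kupffer cell and macrophage genes, 8 were higher and 2 lower, at 1.19-fold (1.13 to 1.26), a call that was lost in the first part (log2 ratios of 0.045, 0.37 and 0.25 in the parts), with C1qc at 4.62-fold and Fcgr1 at 2.39-fold higher, Msr1 at 1.47-fold lower, and Mrc1 at 1.32-fold lower in all reads but with a log2 ratio of 0.12 in the first part. Of 16 stellate cell and fibroblast genes, 9 were higher and 4 lower; Pdgfrb was 2.99-fold and Ngfr 2.67-fold higher, Reln and Dcn were 2.07-fold and 1.59-fold lower, and the pooled ratio of 1.04 (0.998 to 1.08) was not distinguishable from 1. Reln held 2603 of the 5325 bulk reads, the median of members was 0.60, and the pooled log2 ratio of stellate cell and fibroblast markers was called higher, at 0.23, with the median window set to 1. Of 9 cholangiocyte genes, 4 were higher, among them Krt7 at 1.70-fold and Epcam at 1.61-fold, and 2 were lower, Pkhd1 at 2.98-fold and Cftr at 1.86-fold. As Pkhd1 held 2348 of the 4364 bulk reads, the cholangiocyte list was 1.47-fold lower pooled (1.41 to 1.55) with a median of members of 0.40, the opposite sign. The medians of these 5 lists lay at the 99.9th, 99.97th, 99.2nd, 99.9th and 96.5th percentiles, in the order given.

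Gene families and the remaining lists went different ways. Zinc finger genes were poor in macroH2A1: of 203, 174 were lower and 7 higher, at 1.72-fold lower pooled (1.69 to 1.75), and none of 10000 random lists had as low a median as their log2 ratio of -1.91. Some zinc finger genes lie in clusters, so random lists of genes drawn singly can overstate how rare their median is. Zfp60 and Zfp568 were 13.3-fold and 8.78-fold lower, against Zfp827 at 2.88-fold and Zfp462 at 1.78-fold higher. Of 57 vomeronasal receptor genes, 38 were lower and none higher, at 1.53-fold lower (1.46 to 1.59) and the 88.6th percentile, with Vmn2r60 3.08-fold and Vmn2r94 2.55-fold lower, and Vmn2r83 and Vmn2r26 at 1.31-fold and 1.18-fold with intervals that include 1. The olfactory receptor list was 1.31-fold lower (1.26 to 1.35), a call that was lost in the first part (log2 ratios of -0.13, -0.39 and -0.40 in the parts). The pooled log2 ratio of olfactory receptors was -0.14 without the first 1 kb of genes. Only 16 members had enough reads to be called, of which 2 were higher, as Olfr374 at 1.75-fold and Olfr56 at 1.28-fold, and 3 lower, among them Olfr631 at 2.09-fold and Olfr558 at 1.64-fold; its median lay at the 95.4th percentile. Receptor genes have near copies, and only uniquely placed reads were counted. Of 36 overlapping transcripts of the protocadherin clusters, 17 were lower and none higher, at 1.12-fold lower (1.10 to 1.14) and the 68.5th percentile. The call was lost when the median window was set to 1, with the ratio just on the other side of 1. All 36 overlap another annotated gene, so that reads are counted for several of them. The count, the interval and the percentile take these shared reads as independent, so that the interval is too narrow. The 22 other members, each with fewer than 60 reads and together with 173 and 375, had a pooled log2 ratio of -1.01. Pcdha1 and Pcdha3 were 1.41-fold and 1.38-fold lower, and Pcdhga11 and Pcdhgb7 stood at 1.13-fold and 1.11-fold. Against lists matched on GC content instead, the vomeronasal, olfactory and protocadherin medians lay at the 96.3rd, 98.96th and 97.7th percentiles. None of 10000 such lists had a median as low as that of the zinc finger genes.

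Of 24 imprinted genes, 13 were higher and 7 lower, at 1.40-fold higher pooled (1.36 to 1.44) and the 98.6th percentile. Only 12 of the 24 overlap no other gene. Over all listed members without such an overlap the pooled log2 ratio was 0.18, against 0.48 for the whole list. The neighbours Igf2 and H19, which are expressed from opposite parental chromosomes in the fetus, were 5.98-fold (4.49 to 8.10) and 4.38-fold (2.41 to 8.52) higher, with log2 ratios in the parts of 0.90, 2.47 and 3.19 for Igf2 and 1.73, 2.41 and 1.99 for H19, and Ube3a and Mest were 4.47-fold and 4.26-fold lower; all 4 overlap another annotated gene. Of 27 cell division genes, 12 were lower and 4 higher, at 1.18-fold lower (1.13 to 1.24) and the 89.1st percentile, a call that was lost in the first part (log2 ratios of -0.20, -0.39 and -0.20 in the parts), from Mcm3 and Ccna2, 8.67-fold and 5.26-fold lower, to Kif23 and Bub1b, 1.72-fold and 1.68-fold higher. Among 3 histone variant genes, H2afv was 5.88-fold lower like H2afy, and H2afy2, the gene of macroH2A2, was 1.77-fold higher (1.52 to 2.07); the list was 1.44-fold lower (1.29 to 1.61), at the 2.40th percentile. This pooled value rests on H2afy2, which held 448 of the 545 macroH2A1 reads: the median of members was -2.56, and the members that overlap no other gene had a pooled log2 ratio of histone variant genes of -2.46. The replication-dependent histone genes, mostly too short for single calls, were 1.52-fold lower pooled (1.26 to 1.85), a call that was lost in the second part (log2 ratio -0.51). The 1 member with enough reads, Hist1h2be, stood at 0.786 (0.616 to 1.00) and at the 61.8th percentile of single genes matched on reads. Among the other named genes, B230206F22Rik, Eef2, Elovl3, Nrap, Syn2, Mrc1, Olfr56, Ccna2, H2afy2 and Hist1h2be also overlap another annotated gene.

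The authors' deposited table, which gives a fold change of RPKM and an adjusted p per transcript, was set beside these counts. In the authors' deposited table, 18379 of 26339 transcripts had an adjusted p below 0.05, of which 4774 were higher, 13357 lower and 248 had no fold change. In the authors' deposited table, 857 of the 882 X-linked transcripts below that threshold were higher (97.2%), against 3917 of 17492 autosomal ones. For H2afy the authors' deposited table gives a fold change of -6.88 with an adjusted p of 2e-71, and for Xist -1.82 with an adjusted p of 0.000481. Alb, which was undecided here, has a fold change of -1.74 and an adjusted p of 0.0283 in the authors' deposited table. Across 14364 genes, which are not independent replicates, the log2 ratios computed here and the authors' had a Spearman rho of 0.99986 and differed by 0.11 at the median, the X being part of the library size in the latter. The deposited p-values compare 2 libraries, not repeated preparations.

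The third comparison places the difference around transcription start sites of 20302 autosomal genes. MacroH2A1 nucleosomes thinned out toward the start site more than bulk nucleosomes did. Within 200 bp of the start, the macroH2A1 read density was 0.620 of that in the flanks 2 to 3 kb away and the bulk density 0.835, so that the ratio was 1.35-fold lower at the start (0.742 of the flanks, 0.730 to 0.754). The lowest ratio in 50 bp steps was 0.735, at 125 bp into the gene. The flanks differed from each other: upstream the ratio was 1.28-fold relative to all autosomal reads and downstream 1.02-fold. No minimum length was set, so the downstream flank lies beyond the end of the shortest genes. Relative to both flanks together, the ratio at the start was 0.518 for hepatocyte genes (0.404 to 0.663), 0.663 for ubiquitous, proteasome, ribosomal and respiratory genes together (0.509 to 0.857), 0.608 for neuronal genes (0.469 to 0.783) and 0.717 for muscle, germ cell and developmental genes (0.633 to 0.813). These 4 intervals overlap. At the ubiquitous, proteasome, ribosomal and respiratory genes the window at the start was lower than the upstream flank but not lower than the downstream flank. Relative to all autosomal reads the ratio was 0.928 upstream, 0.391 at the start and 0.266 downstream. The window at the start also holds 200 bp of upstream sequence. In the 63 of these genes of 10 kb or more, the first 1 kb stood at 0.142 (0.0919 to 0.211), against 0.187 to 0.251 in the parts of the body. Hepatocyte genes had 1.56, 0.612 and 0.803, neuronal genes 1.03, 0.594 and 0.933, and muscle, germ cell and developmental genes 1.86, 1.37 and 1.97. The last 2 sets were separated after their values were seen.

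The size of the drop depended on the sequencing part, with log2 values of -0.97, -0.48 and -0.34 in the first, the second and the third part. In the first part reads were denser at start sites than in the flanks in both libraries, 1.25 times in macroH2A1 and 2.44 times in bulk.

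**Figure D4:**
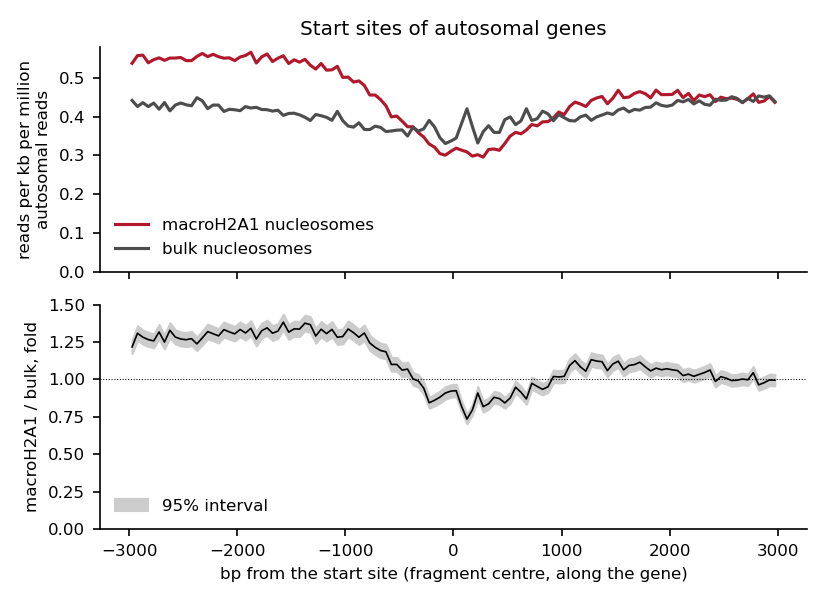
Read density of macroH2A1 (red) and bulk (grey) nucleosomes in 50 bp steps around 20302 autosomal start sites (upper panel, RPKM with autosomal reads as the library size) and their ratio with its 95% interval (lower panel, fold), against the distance of the fragment centre from the start site in bp along the gene. The ratio is lowest, 0.735, at 125 bp and is higher upstream than downstream.

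Along genes of 10 kb or more, the ratio changed at the gene's ends. Over 12397 autosomal genes it was 1.27-fold in the 5 kb upstream, 0.849 in the first 1 kb, and then declined along the gene body from 0.875 in the first of 10 equal parts to 0.706 in the last, before 0.819 in the 5 kb downstream. The 63 ubiquitous, proteasome, ribosomal and respiratory genes of this length were low from end to end: 7.06-fold lower in the first 1 kb (4.75 to 10.9) and between 5.34-fold and 3.99-fold lower in every part of the body, against 0.878 (0.810 to 0.953) upstream and 0.599 (0.554 to 0.647) downstream. The 67 hepatocyte genes stood at 1.36-fold upstream, 0.740 (0.608 to 0.899) in the first 1 kb, and between 0.649 and 0.393 in the body. Genes of other tissues were split into 2 sets after their values were seen, since the long neuronal genes hold most of the reads. The 88 muscle, germ cell and developmental genes stood at 1.61-fold upstream, 1.27-fold in the first 1 kb (1.13 to 1.43), 1.46-fold to 1.25-fold in the body and 1.5-fold downstream. The 66 neuronal genes stood at 0.998 upstream, 0.912 in the first 1 kb (0.778 to 1.07), 0.708 to 0.825 in the body and 0.850 downstream.

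**Figure D5:**
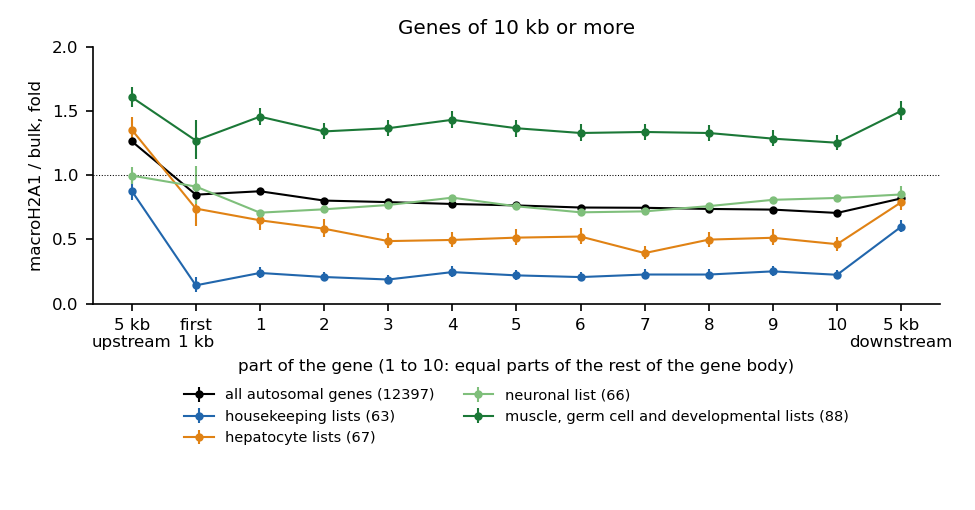
Ratio of macroH2A1 to bulk reads (vertical axis, fold, with 95% intervals) from 5 kb upstream through the first 1 kb and 10 equal parts of the rest of the gene body to 5 kb downstream, pooled over genes of 10 kb or more. Housekeeping lists (ubiquitous, proteasome, ribosomal and respiratory genes; blue) lie at or below 0.251 throughout the gene body, hepatocyte lists (orange) between 0.649 and 0.393, the neuronal list (light green) between 0.708 and 0.825, muscle, germ cell and developmental lists (dark green) between 1.25 and 1.46, and all autosomal genes (black) fall from 0.875 to 0.706.

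The fourth comparison asks how the distribution varies over large regions. Whole megabases of the autosomes were rich or poor in macroH2A1: of 2406 windows of 1 Mb, 793 were higher and 1425 lower, ranging from 0.270 to 3.21-fold. The highest window, on chromosome 9 from 61000001 to 62000000 with Glce, Kif23, Paqr5, Rplp1 and Tle3, at 3.21-fold (3.13 to 3.30), was the only one at or above the X median. It was followed by chromosome 4 from 55000001 to 56000000 (Klf4, Rad23b and Zfp462; 2.64-fold), chromosome 6 from 100000001 to 101000000 (Gxylt2, Ppp4r2, Rybp and Shq1; 2.56-fold) and from 53000001 to 54000000 (Chn2, Cpvl and Creb5 among 5 genes; 2.49-fold), and chromosome 19 from 44000001 to 45000000 (Pax2 and the Scd1 to Scd4 genes among 17; 2.34-fold). The lowest was a gene-free window on chromosome 3 from 24000001 to 25000000, 3.71-fold lower (3.43 to 4.02). Next came windows filled by the very long genes Immp2l on chromosome 12 from 42000001 (3.19-fold lower) and Park2 on chromosome 17 from 11000001 (2.63-fold), and windows on chromosome 13 from 17000001, with Cdk13 and Rala (2.66-fold), and from 67000001, with a cluster of zinc finger genes (2.63-fold). On X the highest windows were from 10000001 (3.93-fold) and from 11000001, with Bcor and Med14 (3.68-fold), and the lowest from 120000001, with Vmn2r121, at 1.09-fold (0.968 to 1.22) and from 30000001 at 1.21-fold.

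The SD of the log2 ratio over autosomal windows was 0.50, against 0.0351 from counting error alone, and neighbouring windows were correlated (r = 0.524 across windows, which are not replicates). The ratio rose with the GC content of the window, from 0.659 in the fifth of windows poorest in GC to 1.27-fold in the richest (Spearman rho 0.694 across windows), and less with the share of the window covered by genes (rho 0.269). The reads themselves had nearly equal mean GC contents, 47.1% in macroH2A1 and 46.9% in bulk, with SDs over reads of 10.0 and 9.98 percentage points in the third part, the only one whose read sequences were used. With a quadratic GC trend removed, the SD was 0.37 and the correlation of neighbours 0.26.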

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

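Reads placed on the Y chromosome, which no comparison uses and which livers of female mice should not give, were above the limit of 3 that a count of 0 allows: 517 in the macroH2A1 library and 937 in the bulk library. Of these, 39.1% (95% Wilson interval 35.0 to 43.3%) and 39.4% (36.3 to 42.5%) had no mismatch, against 83.4% and 84.0% of the reads on X. No explanation was tested.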

How the results depend on the processing

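Use of each sequencing part alone and of reads without a mismatch was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there was 1 library per group, and for the same reason leaving out each library in turn was not possible.

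The X chromosome stayed above the autosomes in every alternative run, against a log2 ratio of 1.45 as reported. The log2 ratio was 1.43 with 1 read per position and strand, 1.58 as a median of windows, 1.77 matched on GC content, 1.83 in gene bodies, where the autosomes are low, 1.23 outside them, and 2.25 as a median of genes from the authors' deposited RPKM values. It was 1.26, 1.40 and 1.49 in the first, the second and the third part, and 1.48 without mismatches. The drop at start sites kept its sign, at a log2 ratio of -0.40 with reads placed at their 5′ end, -0.36 within 500 bp, -0.47 for genes with no other start within 5 kb, -0.97, -0.48 and -0.34 in the parts in order, and -0.36 without mismatches. The SD over autosomal windows was 0.80 for 100 kb and 0.57 for 500 kb windows, 0.37 with the GC trend removed, and 0.42 and 0.52 in the first and the third part. The correlation of neighbours was 0.26 with the GC trend removed and 0.476 in the first part. The causes of these shifts were not tested.

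Fewer genes reach a call where fewer are tested or each has fewer reads. The count of genes higher in macroH2A1 nucleosomes, 4042 as reported, was 943 in the first part and 2101 in the second. The count of genes lower in macroH2A1 nucleosomes, 8020 as reported, was 1161 and 3334 in these parts and 4516 with a minimum of 200 reads. The balance moved too. The share of higher genes among called genes was 33.5% as reported. It ran from 30.4% with the X counted in the library size to 44.8% in the first part. It was 38.7% in the second part and 39.5% with a minimum of 200 reads. Of 30 autosomal lists, 9 had a pooled interval above 1 and 18 below; over the alternatives these were 8 to 12 and 15 to 20. For all 33 lists, 409 of 428 alternatives were counted as unchanged, 5 lost and 11 gained the call, and 3 turned. A turn was counted only for a list called as reported. A list without a call counted as unchanged while it gained none, whatever its sign. Medians of members, which have no interval, were compared by sign and for called lists only. The losses were periportal genes (-0.10) with the median window set to 1, Kupffer cell (0.045), olfactory receptor (-0.13) and cell division (-0.20) genes in the first part, and replication-dependent histones (-0.51) in the second part. The turns were protocadherins to 0.014, without a call, with the median window set to 1, and, as medians of members, cholangiocyte markers to 0.40 and X-linked escape genes to -0.51. Lists without a call changed sign too. With the X in the library size, male-predominant genes went from 0.0039 to -0.10 and stellate cell markers from 0.05 to -0.05. With the median window set to 1, female-predominant genes went from -0.03 to 0.14. For 149 named genes, 1343 of 1420 alternatives were unchanged by the same rule, 53 lost and 21 gained the call, and 3 turned, all in the first part: Cyp2f2 (-0.0052), Mrc1 (0.12) and Emcn (0.25). For these the cause was not tested. Another 80 gave no value, for too few reads or a count of 0. Depth limits short genes: 14364 of 21229 genes reached 60 reads.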

Other observations

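The division of autosomal genes at the dip of their distribution, and the tests of the spread of X genes and of X-linked ubiquitous or liver genes, of single sequencing parts and of bulk density, and the use of members that overlap no other gene for flanks, were chosen after the result was seen.

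The neighbourhood of a gene and the gene itself had different ratios, and the gap differed between groups of genes. In gene-free sequence within 50 kb of 59 ubiquitous, proteasome and oxidative phosphorylation genes, macroH2A1 was 1.34-fold higher than the autosomal level (1.31 to 1.37), while the genes themselves had a log2 ratio of -2.16. Around developmental transcription factor genes the flanks were 1.72-fold higher and the genes differed from them by only -0.03 on the log2 scale (-0.06 to 0.01), and around keratin genes the flanks were 1.83-fold higher and the difference was 0.0062 (-0.06 to 0.07). Hepatocyte genes lay between, at -1.28 for secreted proteins and -1.55 for enzymes and transporters, with flanks 1.32-fold and 1.55-fold higher. Zinc finger genes differed from their flanks by -0.91. Vomeronasal receptor genes lay in regions that were low altogether, with flanks at 0.679 and a difference of -0.09. With only the members that overlap no other gene, the differences were -2.58 for the 53 ubiquitous, proteasome and oxidative phosphorylation genes, -0.04 for developmental genes, 0.09 for keratins, -1.23 and -1.48 for the hepatocyte lists, -0.90 for zinc finger genes and -0.09 for vomeronasal receptors.

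The lower of the groups of autosomal genes, 6181 of 13750 (45.0%), was made up of different shares of the lists. It held 18 of 20 ubiquitous, 20 of 21 proteasome, 19 of 20 oxidative phosphorylation and 148 of 203 zinc finger genes, but none of 36 muscle, 27 germ cell, 78 developmental, 43 keratin, 28 lymphocyte, 16 Kupffer cell or 20 endothelial genes, and 1 of 67 neuronal genes. Hepatocyte lists were divided: 13 of 37 secreted protein genes, 19 of 37 enzyme and transporter genes and 15 of 29 lipid genes were in the lower group. The position of the dip varied with the part: it lay between -1.0 and -0.75 in the first part, where the peaks held 235 and 350 genes and the lower one lay between -1.5 and -1.25. The lower peak was between -2.25 and -2.0 in the second part and between -2.5 and -2.25 in the third part. The 3 parts had 20.2%, 36.9% and 44.4% of the genes with enough reads in that part below the same dividing value.

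The higher ratio of the X chromosome stayed at a log2 value of 1.77 against autosomal windows of the same GC content, which argues against base composition, and at 1.26 in the lowest of the 3 sequencing parts, which argues against a single part. The amount of DNA of a chromosome enters both libraries, as the bulk nucleosomes are the starting material, and so cancels in the ratio. Any other factor that multiplies the ratio of all genes of a chromosome alike would keep their spread on the log2 scale. On X, 8 of 614 genes (1.3%, Wilson interval 0.662 to 2.55%) lay more than 1 below the median log2 ratio of X genes. Of autosomal genes, 4723 of 13750 (34.3%, 33.6 to 35.1%) lay as far below theirs. These shares argue against a multiplying factor as the whole cause. A contribution added alike to every X gene would narrow the spread, so the shares cannot argue against it. The X-linked ubiquitous or liver list, which mixes the 2 kinds of genes, lay 0.072 above all X genes in median log2 ratio (0.022 to 0.16), and autosomal ubiquitous genes lay at -1.80 against all autosomal genes. Base composition, a single part or a multiplying factor does not account for the whole excess. A part of it from a multiplying factor, and any share from a contribution added alike, are not excluded. For the rest, a candidate explanation is that macroH2A1 covers the genes of the inactive X whatever their use elsewhere; the libraries do not separate the X chromosomes of a cell, so it was not tested directly.

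The low ratio of ubiquitous, proteasome and oxidative phosphorylation genes was reached by 1 of 10000 lists matched on GC content for oxidative phosphorylation genes and by none for the other lists, the highest of the 3 percentiles being 0.01. Their difference of -2.59 from flanking sequence (-2.66 to -2.51) argues against large regions that are low as a whole. Their bulk nucleosome density, 0.836, 0.802 and 0.888 times that of the median gene in the order named, argues against a ratio lowered by a high bulk count. These values are consistent with a loss or lack of macroH2A1 within the bodies of genes in wide use, a hypothesis found and examined on the same data and without a measure of transcription.

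Secreted liver protein genes were less low than ubiquitous genes by 1.80 in median log2 ratio, and by 1.25 (0.93 to 1.61) once the trend of all genes with GC content and length was removed. GC content and length therefore do not account for the whole difference, though the lower limit is below the bound of 1 set beforehand. Cells of other types, which do not use these genes, could raise them: of 74 members of the hepatocyte lists, 0 had an upper limit below the ubiquitous median of -2.57, as that explanation predicts. Only 1 of 20 ubiquitous genes meets that bound, so that 3.7 members would be expected if both were alike, a condition added after the 0 was seen, and the explanation stays open.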
